A study of Mus musculus with 34 samples.

How the data were processed

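RNA from the neocortex and the hippocampus of mice was measured on Affymetrix oligonucleotide arrays, 1 array per region and mouse. Per the labels' protocols, mice were injected intraperitoneally on postnatal day 23 and killed on postnatal day 30, 1 week later. Kainate, an agonist of kainate-type and AMPA-type glutamate receptors that provokes seizures, was given 3 times at 15 mg/kg. Nicotine, an agonist of nicotinic acetylcholine receptors, was given 3 times at 10 mg/kg. Injections were 2 h apart, and control mice received saline. There were 6 saline, 5 kainate and 6 nicotine mice, which gives 34 arrays in 6 groups. Total RNA was extracted with TRIzol, and 12 µg per sample was turned into biotin-labelled cRNA, per the labels' protocols.

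The deposited values are signal intensities on a linear scale, made by the authors with MAS5, per the submitters' processing notes, which give no version. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common level. The 2% trimmed mean of each array lay between 1000.5 and 1000.6, so the arrays had been scaled to about 1000. The median signal of an array ranged from 375.8 to 438.6. In the hippocampus it ran from 380.6 to 390.9 with saline, 403.1 to 438.6 with kainate and 394.2 to 434.6 with nicotine. Every drug array there lay above every saline array, so the choice of scaling bears on the hippocampal comparisons with saline. Detection calls were not used here, so dim probe sets could be handled only by their level. Because each array is scaled to 1 mean, a rise of very bright probe sets lowers all others on that array, and the higher and lower calls are relative to that scale.

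The table holds 12488 probe sets. The 66 control probe sets were left out, which leaves 12422. Of these, 10833 had 1 gene symbol in the platform annotation, 396 had several and 1193 had none, and no gene was named from a probe set with several. Entrez identifiers matched 10817 of the named probe sets to the reference gene table, and 8251 genes were named in all. Where a gene has several probe sets, the one with the highest mean log2 value over all arrays is given, and others are mentioned where they disagree. Correlations between pairs of arrays of log2 values ran from 0.916 to 0.969, and 0 pairs of arrays held identical values. The number of arrays limits the precision. The median standard error of a log2 fold change was 0.163 for kainate in the neocortex and 0.171 in the hippocampus.

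Fold changes were computed on log2(signal + 16), which understates the change of dim genes. The authors' scaling was kept. Probe sets were tested if their mean lay at or above the 30th percentile of the arrays in the fit, which left 8695 per comparison. limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3 gave fold changes, standard errors (SE) and p-values. Adjusted p-values are limma's with the Benjamini-Hochberg method, and a probe set was called at an adjusted p under 0.05. Comparisons of treatments used the 17 arrays of 1 region, which share 1 estimate of the spread. The comparison of saline hippocampus with saline neocortex, and the tests of whether a drug effect differed between regions, used all 34 arrays. Per the series design both regions were taken from these mice, but the labels do not say which arrays share a mouse, so these tests treat the arrays as independent. The p-values measure the spread between mice and their arrays within a group. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

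The comparisons, the gene lists, the rule for named genes and the first group of alternatives below were chosen before the data were examined. The 29 gene lists held 749 members, of which 536 were measured. They covered reactive astrocytes, astrocytes, microglia and macrophages, myelin of oligodendrocytes, oligodendrocyte precursors, interneurons, excitatory neurons, dentate granule cells, CA pyramidal cells, endothelial and vascular cells, blood cells, choroid plexus and meninges, and striatum and thalamus. Further lists held immediate early genes, neuropeptides and trophic factors, glutamate receptors, GABA receptors, nicotinic and other cholinergic genes, potassium and sodium channels, synaptic adhesion and plasticity, heat shock and endoplasmic reticulum stress, interferon response and antigen presentation, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, neurogenesis and cell cycle, glucocorticoid targets, the circadian clock, and cell death and injury. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 27 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were counted by their adjusted p over all probe sets and adjusted over the list alone.

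Genes were named by rule. For each drug against saline these were the 12 highest and 12 lowest fold changes among called probe sets with 1 symbol, or the 6 smallest p-values, given as values, where fewer than 12 were called. Up to 4 members of each list with the smallest p were added, together with the tested kainate, AMPA and nicotinic receptor subunits and Npy, Bdnf, Gfap and Fos. The 6 highest and 6 lowest called were named for kainate against nicotine and for differences between regions, and 10 and 10 for the saline regions.

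The procedure was tested on simulated data with 200 changed genes among 8695. For kainate in the neocortex it recovered 46.3% of genes changed by 0.5 on the log2 scale, 73.1% at 1 and 98.5% at 2, and for nicotine in the neocortex 49.3%, 80.6% and 98.5%. In the hippocampus it recovered 29.9%, 68.7% and 97.0% for kainate and 29.9%, 82.1% and 100% for nicotine. With no simulated change, 0 probe sets were called in each of these comparisons. The simulation drew each probe set independently from a normal distribution and left out correlation between genes and any structure among the arrays. That 0 therefore does not show how often real arrays give false calls. In random regroupings of the real arrays, 7 to 10 of 100 splits gave calls in these comparisons. The recovered shares hold for 200 changed genes.

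Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a 50th percentile filter, array quality weights, robust eBayes, only the 2 groups compared, all 34 arrays, the replicate number as a block, and each array left out in turn. Others were chosen after seeing the data. The signals of 9 bacterial hybridization controls split the arrays of each region into 3 clusters, each holding all 3 treatments. The comparisons were therefore repeated with the cluster as a block, within the largest cluster, without the neocortex cluster with the brightest controls, and without the 2 hippocampal arrays least correlated with the others. Replicate numbers were not used to pair samples, since the labels do not say that a number marks 1 animal or a shared day.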

Results

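The arrays compared gene expression in the neocortex and hippocampus of young mice 1 week after injections of kainate, nicotine or saline. Each region had 6 saline, 5 kainate and 6 nicotine arrays. Gfap, the intermediate filament of astrocytes, had a signal of 1675 ± 270 (SD, n = 6) in the saline neocortex and 3801 ± 340 (SD, n = 6) in the saline hippocampus.

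The comparison of the saline hippocampus with the saline neocortex describes the regions before any drug. Dsp and Pkp2, which encode the desmosomal proteins desmoplakin and plakophilin, were 7.02-fold and 4.85-fold higher in the hippocampus (log2 fold changes 2.81 ± 0.24 SE and 2.28 ± 0.18 SE). Also higher were Npy2r, a receptor of neuropeptide Y (5.36-fold), Lct (5.32-fold), Zbtb20, a transcription factor of hippocampal projection neurons (4.39-fold). Calml4 (4.01-fold), Nnat (3.99-fold), Agt, angiotensinogen (3.93-fold), and Crym (3.69-fold) were higher as well. Lower in the hippocampus were Tnnc1 (9.98-fold), the transcription factor Mef2c (4.53-fold), Cux2, a transcription factor of upper cortical layers (4.59-fold). So were Cntn4 (4.82-fold), Dtl (4.35-fold), Igfbp6 (4.13-fold), Rgs4, a regulator of G-protein signalling (3.83-fold), Pcdh7 (3.82-fold) and a probe set assigned to Trbv1 (5.21-fold). In each of these genes but Pcdh7 the 6 hippocampal arrays lay beyond all 6 neocortical arrays, which 0.216% of random regroupings would give. Of all 8695 probe sets, 540 were so separated, where 18.8 would be expected. The dimmer region lay below the filter level of 130 for Dsp, Calml4, Tnnc1, Cntn4, Cux2 and Dtl, so the sizes of their folds depend on the pseudocount. The largest of these limma adjusted p-values was 0.00815, for Calml4. Myl4 was lower by both of its probe sets, with log2 fold changes of −1.05 for the brighter and −2.72 for the dimmer. Tdo2, an enzyme of tryptophan breakdown, was higher by its dimmer probe set only (2.20, against 0.43 with an adjusted p of 0.556 for the brighter).

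In all, 917 of 8695 probe sets differed between the saline regions, 466 higher in the hippocampus (393 genes) and 451 lower (373 genes), and 722 with the control cluster of the arrays as a block. Astrocyte genes were higher in the hippocampus, with 10 of 18 tested members higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 5.72e-05, 0.00518 with an estimated correlation). Of 8 CA pyramidal genes, 4 were higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.0088, 0.0267 with an estimated correlation). Lower in the hippocampus were immediate early genes (10 of 26 lower and 1 higher, 13 and 1 adjusted over the list alone, adjusted p = 5.72e-05, 0.0267 with an estimated correlation). So were neuropeptides and trophic factors (7 of 22 lower, 7 lower and 2 higher adjusted over the list alone, adjusted p = 0.000307, 0.00309 with an estimated correlation) and the circadian clock (4 of 14, 5 adjusted over the list alone, adjusted p = 0.00156, 0.00638 with an estimated correlation). The calls of 5 further lists were lost with an estimated correlation. These were myelin genes (5 of 14 higher, 9 adjusted over the list alone, adjusted p = 0.00018, then adjusted p = 0.0893 with an estimated correlation), ribosomal proteins (3 of 15 higher, 7 adjusted over the list alone, 0.000307, then 0.0807) and synaptic adhesion and plasticity (6 of 19 lower and 1 higher, 7 and 1 adjusted over the list alone, 0.00176, then 0.0807). The others were potassium and sodium channels (5 of 18 lower and 1 higher, 7 and 2 adjusted over the list alone, 0.0114, then 0.141) and interneurons (4 of 19 lower and 2 higher, 5 and 2 adjusted over the list alone, 0.018, then 0.0773). The channel list was also not called without saline hippocampus replicate 2 (adjusted p = 0.05), nor the interneuron list with the 50th percentile filter (range 3.9e-05 to 0.0896). Fry called 15 lists, against 10 by camera.

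In the hippocampus kainate raised genes of microglia, antigen presentation and astrocytes and lowered genes of cholesterol synthesis. Mpeg1, a pore-forming protein of macrophages, rose from a signal of 725.6 ± 229 (SD, n = 6) to 5740 ± 1410 (SD, n = 5), which is 7.87-fold. Gfap rose 4.69-fold, from 3801 ± 340 to 17940 ± 2090. The lysosomal protease Ctss rose 4.29-fold, from 2986 ± 254 to 13110 ± 2870, and C1qa, a subunit of the complement protein C1q, 3.52-fold, from 3171 ± 275 to 11470 ± 2810. The neuropeptides somatostatin (Sst), cortistatin (Cort) and cholecystokinin (Cck) fell. Sst went from 10670 ± 1310 to 6233 ± 536, a log2 fold change of −0.77 ± 0.09 (SE).

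**Figure D1:**
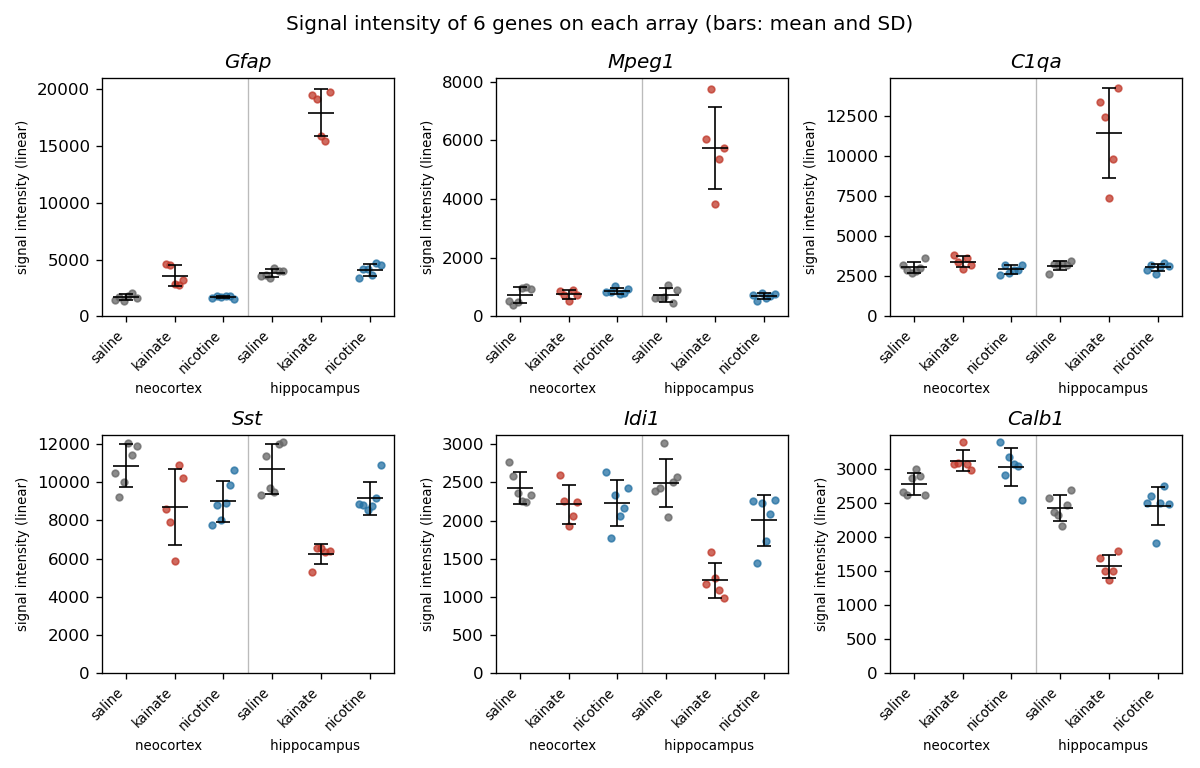
Signal intensity (vertical axis, linear MAS5 units starting at 0) of Gfap, Mpeg1, C1qa, Sst, Idi1 and Calb1 by treatment and region (horizontal axis), with arrays as points, group means as long bars and SDs as whiskers. The kainate hippocampus has mean signals of 17940 for Gfap and 6233 for Sst, against 3801 and 10670 with saline.

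Of 8695 probe sets, 243 were called in the kainate hippocampus against saline, 160 higher (129 genes) and 83 lower (73 genes), and 28 of them had no single gene symbol. With the control cluster as a block 339 were called, 198 higher and 141 lower, and in the largest cluster, with 3 arrays per group, 54. With median centring 443 were called, and most of them were lower, so the balance of directions depends on the scaling. Among the 243 a change of more than 2-fold was seen in 69 of the higher and 6 of the lower. Cst7, cystatin F, an inhibitor of lysosomal proteases in immune cells, rose from a dim 34.87 ± 12.4 to 1254 ± 488 (adjusted p = 6.34e-07). Its log2 fold change depends on the pseudocount, at 4.58 with 16 and 3.65 with 64. High log2 fold changes were also those of H2-K2 (3.57), Mpeg1 (2.98), the immune checkpoint receptor Lag3 (2.93), the interferon-induced Ifit3 (2.82), the lysozyme Lyz2 (2.79), Ly86 (2.34), Gfap (2.23 ± 0.10 SE), Lgals3bp (2.20), Cd52 (2.17) and Ctss (2.10). Their limma adjusted p-values ran from 4.37e-12 for Gfap to 0.00191 for Cd52. In each of them all 5 kainate arrays lay above all 6 saline arrays, which 0.433% of random regroupings would give in one direction or the other. Of all 8695 probe sets, 304 were so separated, where 37.6 would be expected. The receptor gene Csf3r was higher by its dimmer probe set (2.77) and not called by its brighter one (0.26, adjusted p = 0.514). The saline means of Lag3, Ifit3, Lyz2 and the dimmer Csf3r probe set, from 85.97 to 116.4, lay below the filter level of 131, so the sizes of their folds depend on the pseudocount too. Without any 1 of the 5 kainate arrays, with a pseudocount of 1 and with all 34 arrays, Cst7 and Lyz2 fell below the filter and were not tested. H2-K2, H2-K1 and H2-D1 are near-identical members of the class I histocompatibility family, so which member a probe set measured is uncertain.

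The lowest log2 fold changes with called brightest probe sets were those of Alox12b (−1.38, adjusted p = 0.0476), the kinase Zap70 (−1.23, 0.0343), Cort (−1.19, 0.0054), Idi1, an isomerase of the cholesterol pathway (−1.03, 5.42e-05), the kinase Mast3 (−0.92, 0.000725), Rasd1 (−0.84, 0.00137), the immediate early gene Nr4a1 (−0.77, 0.025), Sst (−0.77, 1.16e-05), the calcium release channel Ryr1 (−0.76, 0.0361) and Pkp2 (−0.69, 0.0156), all adjusted by limma. In each of these but Alox12b, where 4 did, the 5 kainate arrays lay below all 6 saline arrays. H2-M10.1 and Ssbp4 were lower by a dimmer probe set (−1.60 and −1.17), while their brighter ones gave 0.51 (adjusted p = 0.118) and −0.37 (adjusted p = 0.0778). The kainate means of Alox12b (103.2) and the dimmer Ssbp4 probe set (91.84) lay below the filter level of 131, so the sizes of their folds depend on the pseudocount. With a pseudocount of 64 Alox12b gave −0.975 and was not called (limma adjusted p = 0.0514). The brighter Ssbp4 probe set was called lower in 4 of 14 alternatives, among them the control cluster as a block (0.0179) and median centring (0.0138, range 0.0138 to 0.449). Dimmer probe sets of Zap70 gave −0.38 and 0.09, neither called. Both dimmer calls depended on single arrays, Ssbp4 on each of the 11 but saline replicate 1 (adjusted p up to 0.112) and H2-M10.1 on saline replicates 3 and 6 and kainate replicates 1 and 2 (up to 0.0685). With 1 array left out, 7 calls named here or below were lost in 6 to 9 of the 11 fits, and each of the 11 arrays ended at least 1 of them: Alox12b (highest adjusted p 0.125), Zap70 (0.114), Nr4a1 (0.0703), Ryr1 (0.0802), Slc32a1 (0.0808), Hspa5 (0.117) and Dnajb1 (0.112). Other alternatives also ended calls, 5 of 12 for Alox12b (adjusted p up to 0.136), 2 of 14 for Zap70 (0.12), 4 of 13 for Ryr1 (0.373), 6 of 14 for Hspa5 (0.12), 3 of 14 for Dnajb1 (0.436) and 2 of 14 for Slc32a1 (0.5). The largest cluster, with 3 arrays per group, ended 33 of 53 calls of genes named for this comparison (adjusted p from 0.0507 to 0.5). Besides Zap70, Ryr1, Slc32a1, Hspa5, Dnajb1 and the dimmer Ssbp4 probe set, these were Lag3, Ifit3, Lyz2, the dimmer Csf3r probe set, H2-M10.1, Cort, Idi1, Rasd1, Nr4a1, Pkp2, S100a10, Aqp4, Mt1, Mt2, Ptprz1, Calb1, Penk, Egr1, Cck, Gabbr1, Kcnab2, Sparc, Ighm, Bgn, Fdps, Hmgcs1 and Sqle. Median centring ended those of Ptprz1 (0.0503, range 0.00669 to 0.297) and Sparc (0.0508, range 0.00124 to 0.165). Without kainate replicate 4 the adjusted p of Pkp2 was 0.0557 and that of Kcnab2 0.0591, and without kainate replicate 5 that of Egr1 was 0.0555.

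Microglia and macrophage genes rose in the kainate hippocampus, with 17 of 22 tested members called higher and 0 lower (20 adjusted over the list alone). Their median log2 fold change was 1.60 (camera adjusted p = 6.97e-45, 1.83e-05 with an estimated correlation). Besides Mpeg1, Ctss and C1qa, the lysosomal membrane gene Laptm5 rose 2.55-fold. Interferon and antigen presentation genes rose too, 10 of 15 (12 adjusted over the list alone), with a median of 0.91 (adjusted p = 4.73e-19, 5.99e-05 with an estimated correlation). B2m, the light chain of class I histocompatibility molecules, rose 3.46-fold, from 2583 ± 1100 to 8815 ± 2890, H2-D1 rose 3.47-fold, H2-K1 3.46-fold and the interferon-induced membrane protein Ifitm3 2.84-fold. Beside these lists, markers of other cell types moved less. The medians were 0.09 for 14 myelin genes (0 called, adjusted p = 0.257) and −0.01 for 21 endothelial and vascular genes (Sparc called higher, adjusted p = 0.813).

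Reactive astrocyte genes rose, 7 of 18 (8 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 3e-11, 0.000464 with an estimated correlation). Serpina3n, an acute-phase protease inhibitor, rose 3.05-fold from 2850 ± 440 to 8681 ± 1020, and the calcium-binding S100a6 and S100a10 rose 2.92-fold and 1.88-fold. Of 18 general astrocyte genes 7 rose (8 higher and 1 lower adjusted over the list alone), with a median of 0.25 (adjusted p = 1.71e-06, 0.00947 with an estimated correlation). Among them the water channel Aqp4 rose 1.83-fold and the secreted chaperone Clu 1.70-fold, from 15610 ± 2130 to 26460 ± 3650. So did the lipid carrier Apoe 1.47-fold, from 48620 ± 4790 to 71270 ± 7680, and the metallothionein Mt2 by 0.59 on the log2 scale. Probe sets that were not called gave −0.10 for S100a10 and 0.41 for H2-K1.

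Cholesterol synthesis genes fell, 6 of 15 (8 adjusted over the list alone), with a median of −0.50 (camera adjusted p = 7.78e-08, 0.00947 with an estimated correlation). Idi1 went from 2491 ± 313 to 1219 ± 229, and the log2 fold changes were −0.62 for the farnesyl diphosphate synthase Fdps, −0.60 for the squalene epoxidase Sqle and −0.54 for the HMG-CoA synthase Hmgcs1. Heat shock and endoplasmic reticulum stress genes fell, 2 of 22 (6 adjusted over the list alone), with a median of −0.21 (adjusted p = 0.000118, 0.0124 with an estimated correlation). The 2 were the chaperone Hspa5 (−0.43) and the co-chaperone Dnajb1 (−0.41). Oxidative phosphorylation genes had a median of −0.17 with 0 of 32 called (7 lower adjusted over the list alone), and camera called the list lower (adjusted p = 5.14e-06). That call was lost at adjusted p = 0.0977 with an estimated correlation.

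Among neuronal genes, 3 of 19 interneuron genes fell, namely Sst, Cort and Slc32a1, the vesicular transporter of GABA (−0.43, adjusted p = 0.0273). The list as a whole was not called (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.0829). Of 22 neuropeptide and trophic genes, Sst and Cck (−0.50, adjusted p = 0.00025) fell and the enkephalin precursor Penk rose (0.87, adjusted p = 0.00184), 2 and 2 adjusted over the list alone, and the list was not called (adjusted p = 0.781). A dimmer probe set of Penk gave 0.40 (adjusted p = 0.53). Calb1, the calcium buffer calbindin of dentate granule cells, fell from 2430 ± 188 to 1572 ± 171 (−0.63 ± 0.10 SE, adjusted p = 0.00048). Its list of 7 dentate granule genes was not called (Penk higher and Calb1 lower, also adjusted over the list alone, adjusted p = 0.813, median −0.01 but mean 0.04). Excitatory neuron genes had a median of −0.14 with 0 of 19 called (2 lower adjusted over the list alone), and camera called the list lower (adjusted p = 0.0168), a call lost at adjusted p = 0.159 with an estimated correlation and without saline replicate 3 or 4 (up to 0.0682), in all in 3 of 16 alternatives other than left-out arrays (range 0.00276 to 0.159). CA pyramidal genes were not called (0 of 8, 1 lower adjusted over the list alone, adjusted p = 0.0893). Of 25 immediate early genes, Egr1 fell from 4272 ± 382 to 2882 ± 403 (−0.57, adjusted p = 0.0135), as did Nr4a1, and the list was not called (3 lower adjusted over the list alone, adjusted p = 0.0531). It was called in 9 of 16 alternatives (range 0.00704 to 0.113).

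The receptor subunits Gria1 to Gria4, Grik1, Grik2, Grik5, Chrna6 and Chrna7 were tested in each region, and 0 of 9 were called for either drug. The smallest adjusted p was 0.0668, for Gria2, the AMPA receptor subunit that limits calcium entry, in the kainate hippocampus (−0.19). Gria2 was called there with the control cluster as a block (0.0248) and with median centring (0.0046), among 3 of 14 alternatives (range 0.0046 to 0.388), as was Gria1 with median centring (0.0447, range 0.0447 to 0.655). The glutamate receptor list was not called there (0 of 13, 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.721, median −0.11 but mean 0.01). The GABA receptor subunit Gabbr1 fell (−0.42, adjusted p = 0.00742), the only one of 9 GABA receptor genes called (1 adjusted over the list alone, adjusted p of the list 0.675). So did the potassium channel subunit Kcnab2 (−0.36, adjusted p = 0.017) among 18 potassium and sodium channel genes (1 adjusted over the list alone, adjusted p of the list 0.809). Npy in the kainate hippocampus had a signal of 3165 ± 208 against 2548 ± 247 and was not called (0.32, adjusted p = 0.0568), though it was without saline replicate 2 (0.0373) with the control cluster as a block (0.0354), quantile normalization (0.0479), array weights (0.0264), all 34 arrays (0.0178) and the 50th percentile filter (0.0498), among 6 of 14 alternatives (range 0.0178 to 0.473). Nor were Fos (−0.57, adjusted p = 0.383) and the neurotrophin Bdnf (−0.18, adjusted p = 0.589) called in the main fit. With the replicate number as a block Fos was called lower (−0.71, limma adjusted p = 0.0331).

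Glucocorticoid targets were called higher in the kainate hippocampus (median 0.16, 2 of 18 called, 2 adjusted over the list alone, adjusted p = 0.0266), a call lost at adjusted p = 0.153 with an estimated correlation and without kainate replicate 1 or 5 (up to 0.0883), in all in 3 of those 16 (range 0.00995 to 0.294). The 2 members were the metallothioneins Mt1 and Mt2, which are also in the astrocyte list. The remaining lists were not called by camera at its preset correlation in the kainate hippocampus. Their camera adjusted p-values were 0.721 for blood cells (1 of 7 higher, the immunoglobulin gene Ighm, median −0.07 but mean 0.05), 0.197 for choroid plexus and meninges (1 of 15 higher, the matrix proteoglycan Bgn) and 0.948 for striatum and thalamus (median 0.12 but mean −0.01). They were 0.078 for synaptic adhesion and plasticity, 0.058 for ribosomal proteins, 0.078 for neurogenesis and cell cycle, 0.448 for the circadian clock and 0.0534 for cell death and injury. Adjusted over the list alone, 1 member was higher for blood cells, choroid plexus and meninges, and cell death and injury each, and 0 were called in the others. Some uncalled lists of the kainate hippocampus were called with 1 array left out. This held for immediate early genes (without saline replicate 5 or 6 or kainate replicate 3 or 4, lowest adjusted p 0.0222) and cell death and injury (saline 1, 2 or 6 or kainate 2 or 3, 0.0222). It held as well for ribosomal proteins (saline 5 or kainate 3 or 4, 0.00809), synaptic adhesion and plasticity (saline 1 or 2 or kainate 4, 0.01), CA pyramidal cells (kainate 3, 0.0222) and interneurons (kainate 2 or 4, 0.0446). Among the 16 other alternatives, cell death and injury was called in 8 (range 0.00692 to 0.2), ribosomal proteins in 6 (2e-04 to 0.677) and CA pyramidal cells in 4 (0.0251 to 0.29). Interneurons (0.0327 to 0.375) and synaptic adhesion and plasticity (0.0223 to 0.915) were called in 2 each. Neurogenesis and cell cycle was called by fry alone (0.00703, range 0.00703 to 0.423), and choroid plexus and meninges with the 50th percentile filter alone (0.0484, range 0.0484 to 0.646). In all, fry called 14 of the 27 lists, against 9 by camera. Of the oligodendrocyte precursor genes, too few to test as a list, Ptprz1 rose (0.50, adjusted p = 0.00807), and no cholinergic gene was called. Other probe sets gave 0.21 and 0.29 for Ptprz1, −0.21 for Ighm and 0.62 for Bgn, none of them called. With median centring of each array the median of all probe sets moved from 0.01 to −0.10 and 443 probe sets were called, 130 higher and 313 lower. The medians of the astrocyte, excitatory neuron, heat shock, oxidative phosphorylation and glucocorticoid lists were then 0.14, −0.25, −0.32, −0.28 and 0.05. With the 50th percentile filter those of reactive astrocytes, interferon and antigen presentation and glucocorticoid targets were 0.79, 1.505 and 0.03, and in the largest cluster that of reactive astrocytes was 0.28. The glucocorticoid median was 0.06 without saline replicate 2, and that of excitatory neurons −0.09 with quantile normalization.

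**Figure D2:**
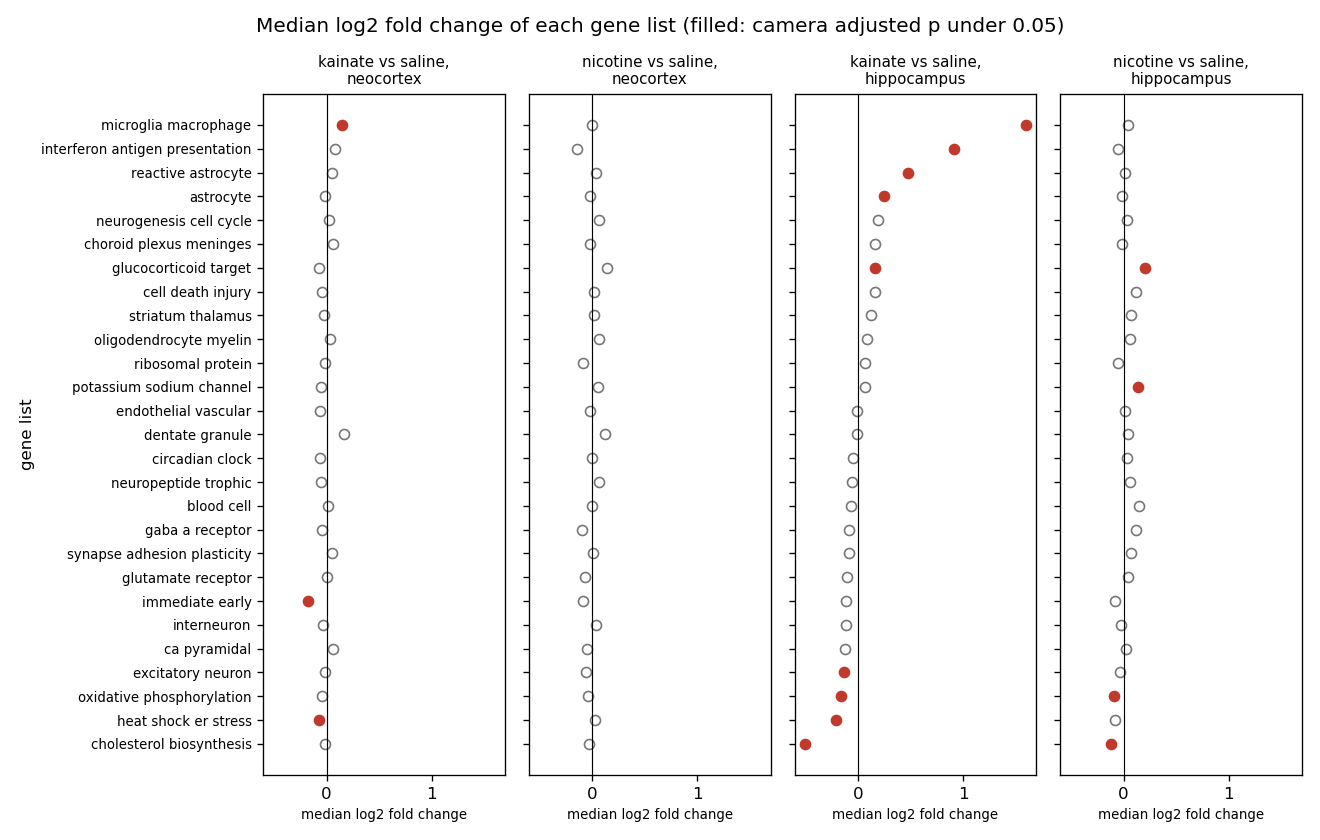
Median log2 fold change (horizontal axis) of each gene list (vertical axis, ordered by the kainate hippocampus) for each drug against saline in each region, filled where the camera adjusted p is under 0.05. The microglia and macrophage list lies at 1.60 in the kainate hippocampus and at 0.15 in the kainate neocortex.

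In the kainate neocortex, Gfap rose 2.10-fold, from 1675 ± 270 (SD, n = 6) to 3594 ± 914 (SD, n = 5). It was the only probe set of 8695 called against saline (log2 fold change 1.07 ± 0.14 SE, limma adjusted p = 0.00139), and all 5 kainate arrays lay above all 6 saline arrays. Of all 8695 probe sets, 49 were so separated, where 37.6 would be expected. A dimmer probe set of Gfap gave 0.83 (adjusted p = 0.34). The next smallest p-values belonged to Ctss (0.49, adjusted p = 0.102), Wfs1, a membrane protein of the endoplasmic reticulum and marker of CA1 neurons (0.49, 0.226), Dio2, the deiodinase that activates thyroid hormone (−0.48, 0.251), Hsd11b1, which regenerates glucocorticoids (−0.60, 0.251) and Cort (−0.79, 0.251), none of which was called. With the control cluster of the arrays as a block 6 probe sets were called, among them Gfap, Ctss (adjusted p = 0.00139, range over the alternatives 0.00139 to 0.48), Nr4a1 (−0.70, 0.000758, range 0.000758 to 0.905) and Cort (0.04, range 0.04 to 0.54). Ctss was also called with quantile normalization (0.0365) and array weights (0.0433), among 5 of 14 alternatives. Beside Gfap, 72 probe sets enriched in the saline hippocampus had a mean log2 fold change of 0.165 ± 0.0568 (SE) in the kainate neocortex, and 58 enriched in the nicotine hippocampus 0.08 ± 0.0437. An unadjusted p under 0.05 was seen for 484 probe sets, where 435 would be expected by chance.

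Microglia and macrophage genes rose as a list in the kainate neocortex, although 0 of 20 were called singly (3 higher adjusted over the list alone). Their median was 0.15 (camera adjusted p = 0.000322, 0.0277 with an estimated correlation), and 16 of 20 were positive. The median was 0.23 without kainate replicate 3. Immediate early genes were called lower (median −0.18, 0 of 26 called, 2 lower adjusted over the list alone, adjusted p = 0.000666), a call lost at adjusted p = 0.458 with an estimated correlation. Heat shock genes were also called lower (median −0.08, 0 of 22 called singly and 0 adjusted over the list alone, adjusted p = 0.0353). That call was lost at adjusted p = 0.517 with an estimated correlation. Without saline replicate 1, 2 or 5 or kainate replicate 4 or 5 the heat shock list was not called, with adjusted p up to 0.361, nor was it in 7 of 16 other alternatives (range 0.00215 to 0.702). Its median was −0.14 without kainate replicate 3, −0.13 without saline replicate 3 and −0.12 without saline 6. The immediate early call was lost by fry as well (0.494, range 7.64e-08 to 0.494). Reactive astrocyte genes, of which Gfap alone was called among 18 (2 adjusted over the list alone), had a list adjusted p of 0.0536, which fell under the threshold without saline replicate 3 or 6 or kainate replicate 3 (lowest 0.0194). It was also called in 5 of 16 other alternatives (range 0.000947 to 0.646). Npy (0.12), Bdnf (−0.01) and Fos (−0.55) had adjusted p-values of 0.903, 0.994 and 0.903.

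The kainate effect differed between the regions for 69 probe sets, 63 of them (54 genes) with a more positive effect in the hippocampus and 6 (6 genes) with a more negative one, and for 102 with the control cluster as a block. The largest differences in log2 fold change were those of Mpeg1 (2.84 ± 0.30 SE, limma adjusted p = 6.96e-08), Ifit3 (2.74, 0.0012), Cd52 (2.51, 0.00209), H2-K1 (1.93, 4.35e-05), Lgals3bp (1.92, 1.44e-06) and H2-D1 (1.72, 1.22e-05). On the saline neocortex arrays H2-D1 was 3272 in replicate 1 and from 1159 to 1509 in the others. In the neocortex alone the log2 fold change of Mpeg1 was 0.14 and that of Ifit3 0.07. The rise of Gfap was larger in the hippocampus by 1.16 ± 0.17 SE (adjusted p = 4.35e-05). More negative in the hippocampus were Msmo1, a sterol oxidase (−0.91, 0.0423), Idi1 (−0.90, 0.00209), Wfs1 (−0.88, 0.00109), Calb1 (−0.80, 6.49e-05), the kinase Cdk14 (−0.58, 0.0226) and the calcium-binding Cpne6 (−0.52, 0.0216). The call of Cpne6 was lost with quantile normalization (0.0988, range over the alternatives 0.00391 to 0.0988). The differences of Sst (−0.42, adjusted p = 0.352) and Egr1 (−0.54, 0.212) were not called. With the control cluster as a block that of Egr1 was (0.0297, range 0.0204 to 0.254). Wfs1 was not called against saline in either region, at 0.49 in the neocortex and −0.39 in the hippocampus (adjusted p = 0.226 and 0.0992). In the hippocampus it was called with median centring (−0.50, 0.0337) and with all 34 arrays (0.0407, range 0.0337 to 0.474).

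By list, the difference was called for microglia and macrophages (11 of 21 higher, 16 adjusted over the list alone, camera adjusted p = 6.36e-42, 4.49e-09 with an estimated correlation), interferon and antigen presentation (4 of 15, 9 adjusted over the list alone, 7.24e-16, 1.25e-05 with an estimated correlation). It was also called for reactive astrocytes (4 of 18, 6 adjusted over the list alone, 5.31e-09, 1.25e-05 with an estimated correlation), astrocytes (4 of 18, 8 higher and 1 lower adjusted over the list alone, 5.75e-07, 0.000478 with an estimated correlation) and cholesterol synthesis (2 of 15 lower, 7 adjusted over the list alone, 5.75e-07, 0.00126 with an estimated correlation). Glucocorticoid targets (2 of 19 higher, 4 adjusted over the list alone, adjusted p = 0.000903, 0.0177 with an estimated correlation) and cell death and injury genes (1 of 15 higher, 3 adjusted over the list alone, adjusted p = 0.0199, 0.0377 with an estimated correlation) also differed. The 2 glucocorticoid members were Mt1 and Mt2 (adjusted p = 0.0423 each), whose calls were lost with median centring (0.299 and 0.239) and with no filter (0.0674 and 0.063). The ranges over the alternatives were 0.00419 to 0.299 for Mt1 and 0.00732 to 0.239 for Mt2. The difference in oxidative phosphorylation genes (0 of 32, 0 adjusted over the list alone, adjusted p = 0.00108) was lost at adjusted p = 0.145 with an estimated correlation and also with quantile normalization (range 0.000291 to 0.145). Uncalled lists that other settings called were excitatory neurons (4 of 12 alternatives, range 0.0219 to 0.312) and ribosomal proteins (3 of 12, 0.00724 to 0.498). Choroid plexus and meninges (0.0184 to 0.312), synaptic adhesion and plasticity (0.0493 to 0.349), CA pyramidal cells (0.0444 to 0.222) and neurogenesis and cell cycle (0.0401 to 0.163) were called in 1 each. The cell death and injury list was not called without kainate neocortex replicate 4 or kainate hippocampus replicate 1 (adjusted p up to 0.065). With 1 array left out, the difference of Msmo1 was lost in 15 of 22 fits (adjusted p up to 0.117), all but those without saline neocortex replicate 1 or 2, kainate neocortex 4 or 5, saline hippocampus 4 or 6 or kainate hippocampus 2. It was also lost with no filter (0.0532, range 0.0122 to 0.0532). That of Cdk14 was lost without kainate neocortex replicate 3 or 5 or kainate hippocampus replicate 2 or 4 (up to 0.0731), and that of Cpne6 without kainate neocortex replicate 4 or 5 or kainate hippocampus replicate 5 (up to 0.0644). Median centring gave 47 probe sets, 35 higher and 12 lower.

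**Figure D3:**
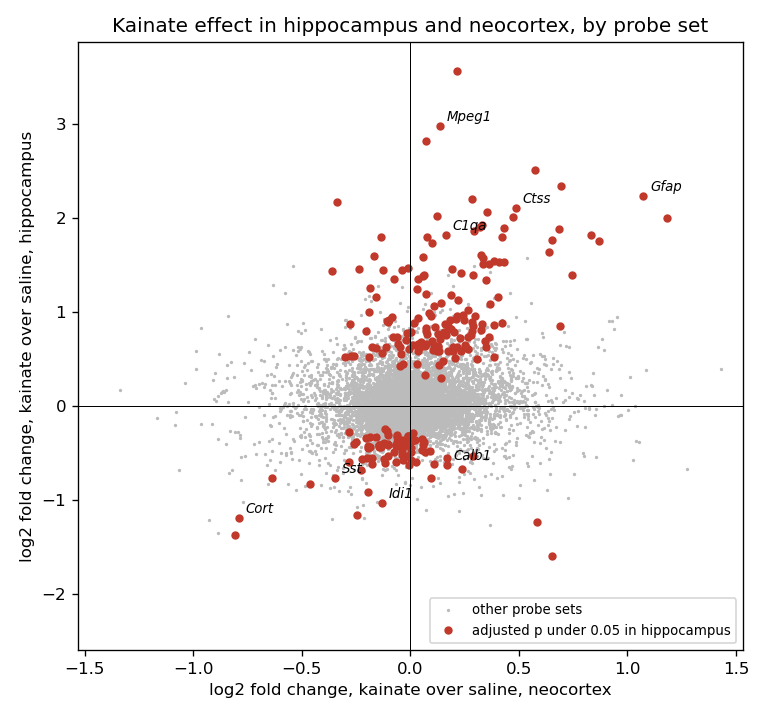
Log2 fold change of kainate over saline in the neocortex (horizontal axis) and the hippocampus (vertical axis) for the 8484 probe sets tested in both, red where called in the hippocampus. Gfap lies at 1.07 and 2.23, while Mpeg1 lies at 0.14 and 2.98.

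Of the probe sets called higher in the kainate hippocampus, 153 were tested in the neocortex, and 117 of them had a positive fold change there, with a median of 0.14 against 0.88 in the hippocampus. Of 83 called lower, 62 were negative in the neocortex, with a median of −0.07 against −0.44. Of all probe sets tested in the neocortex, 51.2% were positive. Over all 8484 probe sets the fold changes of kainate in the regions had a Pearson correlation of 0.115 (Spearman 0.088, covariance 0.00833), and those of nicotine 0.164 (Spearman 0.203, covariance 0.0091). The latter was 0.305 with the 50th percentile filter. These correlations are across probe sets, which are not independent replicates.

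Nicotine gave no called probe set in either region. In the neocortex the smallest p-values belonged to Crb3, a cell polarity gene, with a signal of 941.2 ± 156 against 582.3 ± 112 (SD, n = 6 each, log2 fold change 0.68). They also belonged to Yipf4 (−0.59), the sphingosine kinase Sphk2 (0.52), the helicase Dhx36 (0.62) and dimmer probe sets of Eif3e (1.80) and Gosr2 (0.44), each with a limma adjusted p of 0.26. In each of these the 6 nicotine arrays lay beyond all 6 saline arrays, which choosing the smallest p-values favours. Of all 8695 probe sets, 49 were so separated, where 18.8 would be expected from random regrouping (0.216%). In the nicotine hippocampus 13 were, where 18.8 would be expected. Other probe sets gave 0.47 for Eif3e, 0.14 and 0.01 for Gosr2 and −0.19 for Sphk2, all uncalled. In the hippocampus the smallest p-values belonged to the folate receptor Folr2 (1.22), a dimmer probe set of Nudt4 (0.50), the phospholipase Plcb1 (0.36), Llgl2 (1.41), the adenosine kinase Adk (0.43) and Csn3 (1.55), each with an adjusted p of 0.851. The dimmer Eif3e probe set (77.68) and Csn3 (84.55) had saline means below the filter levels of 128 and 131. limma called 0 probe sets in the nicotine neocortex, with 835 at an unadjusted p under 0.05 where 435 would be expected, and 0 in the nicotine hippocampus, with 504. Array weights and robust eBayes also called 0 in both. Gfap was 1702 ± 128 in the nicotine neocortex (0.04, adjusted p = 0.951) and 4097 ± 504 in the nicotine hippocampus (0.10, adjusted p = 0.908). Npy (0.01 and −0.03), Bdnf (0.25 and 0.02) and Fos (−0.27 and −0.44) were likewise uncalled in the neocortex and hippocampus.

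Glucocorticoid targets were called higher in the nicotine hippocampus, with 17 of 18 members positive and a median of 0.20 (0 called singly and 0 adjusted over the list alone, camera adjusted p = 3.19e-05). That call was lost at adjusted p = 0.0569 with an estimated correlation, and fry gave 0.0279. The members with the smallest p were the receptor co-chaperone Fkbp5 (0.34), Hif3a (0.81) and the transcription factor Klf9 (0.22), each with an adjusted p of 0.851. In the nicotine neocortex 17 of 20 members were positive with a median of 0.14, and the list was not called (adjusted p = 0.0708), though it was without saline replicate 1, 3 or 6 or nicotine replicate 4 (lowest 0.0221). It was also called in 7 of 16 other alternatives, among them the control cluster as a block, quantile normalization and array weights (range 0.0146 to 0.546). In the nicotine hippocampus camera also called oxidative phosphorylation lower (median −0.09, adjusted p = 0.000543) and potassium and sodium channels higher (median 0.13, adjusted p = 0.0232). It called cholesterol synthesis lower (median −0.12, adjusted p = 0.0405), and all 3 lists had 0 members called singly or adjusted over the list alone. All 3 calls were lost, each at adjusted p = 0.482 with an estimated correlation. The channel list was not called without saline replicate 1, 2 or 6 or nicotine replicate 2 or 6 (adjusted p up to 0.185), nor the cholesterol list without saline replicate 1, 2, 3 or 4 or nicotine replicate 2 or 4 (up to 0.22). Of 16 other alternatives, 5 ended the call of channels (range 0.0133 to 0.482), 5 that of cholesterol synthesis (0.00188 to 0.482) and 3 that of oxidative phosphorylation (5.18e-05 to 0.482). The channel median was 0.07 without saline replicate 1 or 2 and 0.25 without saline replicate 5, and that of oxidative phosphorylation −0.05 without nicotine replicate 3. In the largest cluster the medians of channels and cholesterol synthesis were 0.23 and −0.24. With median centring those of channels, cholesterol synthesis and oxidative phosphorylation were 0.07, −0.19 and −0.155. Ribosomal proteins were called lower with median centring alone (0.0443, range 0.0443 to 0.944). Blood cell genes, uncalled in the nicotine hippocampus (adjusted p = 0.148), were called without nicotine replicate 1 or 4 (lowest 0.0331). In the nicotine neocortex 0 of 27 lists were called. The nicotine effect differed between the regions for 0 probe sets by limma, with 328 at an unadjusted p under 0.05, and for 0 with array weights or robust eBayes and 0 of 27 lists.

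Set directly against nicotine, kainate gave 210 called probe sets in the hippocampus, 177 higher (144 genes) and 33 lower (30 genes), and 254 with the control cluster as a block. Cst7 was again higher (adjusted p = 5.66e-06), and its fold again depends on the pseudocount, with nicotine replicate 3 at 304.9 and the other nicotine arrays from 29.3 to 59.7. High log2 fold changes were also those of H2-K2 (3.78), Lyz2 (3.17), Mpeg1 (3.01), Lag3 (2.90) and Ifit3 (2.85), with limma adjusted p-values from 1.71e-09 for Mpeg1 to 0.000235 for Lyz2. Lyz2, Lag3 and Ifit3 had nicotine means below the filter level, from 71.97 to 93.85. The lowest log2 fold changes were those of Alox12b (−1.64), Cort (−1.10), Rasd1 (−1.02), Dnajb5 (−0.78) and Idi1 (−0.71), with adjusted p-values of 0.0148, 0.0117, 0.000156, 0.0309 and 0.00344. The kainate mean of Alox12b, 103.2, lay below the filter level as well. Etfb was lower by a dimmer probe set (−0.93) and not by its brighter one (0.02, adjusted p = 0.993), and that call was lost without any of kainate replicates 1 to 4 or nicotine replicates 1 to 5 (up to 0.105). With 1 array left out the call of Dnajb5 was lost without kainate replicate 1, 3 or 5 or nicotine replicate 2, 3, 4 or 6 (adjusted p up to 0.107). Other alternatives ended the calls of Etfb (5 of 14, range 0.0197 to 0.145), Dnajb5 (3 of 14, 0.00928 to 0.235), Cort (3 of 13, 0.000881 to 0.511) and Alox12b (1 of 12, 0.00038 to 0.0627). The largest cluster ended 26 of 42 calls of genes named for this comparison (0.0511 to 0.706), among them Idi1 (−0.45, adjusted p = 0.634, range 0.000163 to 0.634), Rasd1 (0.097, range 8.74e-05 to 0.097), Lag3 (0.063, range 9.88e-06 to 0.063) and Cst7 (0.0558, range 1.54e-07 to 0.0558). By list, 16 of 22 microglia and macrophage genes (20 adjusted over the list alone), 9 of 15 interferon and antigen presentation genes (11), 6 of 18 reactive astrocyte genes (8) and 7 of 18 astrocyte genes (8) were higher with kainate. Lower were 4 of 15 cholesterol synthesis genes (8) and 1 of 22 heat shock genes (1). Camera called these lists at adjusted p = 1.44e-49, 1.29e-20, 1.33e-12, 3.47e-09, 1.62e-05 and 0.00276, and the highest with an estimated correlation was adjusted p = 0.0484, for heat shock genes. Ribosomal proteins (1 of 15 higher, 2 adjusted over the list alone, adjusted p = 0.000505, then adjusted p = 0.141 with an estimated correlation), excitatory neurons (0 of 19, 0 adjusted over the list alone, lower, 0.00626, then 0.141) and synaptic adhesion and plasticity (0 of 19, 0 adjusted over the list alone, lower, 0.0111, then 0.194) lost their calls. So did interneurons (3 of 19 lower and 1 higher, 5 and 2 adjusted over the list alone, lower, 0.0482, then 0.159) and oxidative phosphorylation (0 of 32, 0 adjusted over the list alone, lower, 0.0482, then 0.363). The synapse list was not called without kainate replicate 1 (adjusted p = 0.0758), nor the interneuron list without kainate replicate 1, 3 or 5 or nicotine replicate 1, 3, 4 or 6 (up to 0.168), nor oxidative phosphorylation without kainate replicate 1, 3 or 4 or nicotine replicate 2, 5 or 6 (up to 0.164). Of 16 other alternatives, 9 ended the call of interneurons (range 0.0266 to 0.418), 8 that of oxidative phosphorylation (0.02 to 0.363), 4 that of the synapse list (0.00353 to 0.423), 2 that of excitatory neurons (0.00127 to 0.218) and 1 that of cholesterol synthesis (1.31e-06 to 0.154). Uncalled lists were called in 6 for choroid plexus and meninges (0.00849 to 0.307) and in 5 for CA pyramidal cells (0.0109 to 0.312). Fry called 12 lists, against 11 by camera.

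In the neocortex, Gfap (1.04, 2.05-fold, adjusted p = 0.0023), Wfs1 (0.62, 3241 ± 301 against 2117 ± 267, adjusted p = 0.0187) and S100a6 (0.61, 1753 ± 294 against 1131 ± 92.1, adjusted p = 0.0381) were higher with kainate than with nicotine by limma, and these 3 probe sets were all that were called. In each of these 3 the 5 kainate arrays lay above all 6 nicotine arrays, but 44 of all 8695 probe sets were so separated, where 37.6 would be expected. With the control cluster as a block 8 were called. Ctss (0.48, adjusted p = 0.0558) was called in 6 of 14 alternatives, among them that block (0.00231), array weights (0.0097), quantile normalization (0.0269) and the 50th percentile filter (0.0416, range 0.00231 to 0.435). Cort (adjusted p = 0.143) was called lower in 2, array weights and that block (0.0276, range 0.0276 to 0.619). Glucocorticoid targets were lower with kainate than with nicotine (median −0.22, 0 of 20 called, 2 lower adjusted over the list alone, camera adjusted p = 3.93e-06, 0.0116 with an estimated correlation) and microglia and macrophage genes higher (median 0.15, 0 of 20, 1 adjusted over the list alone, adjusted p = 0.000363, 0.0194 with an estimated correlation). The glucocorticoid median was −0.10 without kainate replicate 4 and −0.14 with array weights, and the microglia median 0.22 with the 50th percentile filter. Camera called 5 more lists that were lost with an estimated correlation. They were reactive astrocytes (2 of 18 higher, 2 adjusted over the list alone, median 0.01, adjusted p = 0.0321, then adjusted p = 0.0892 with an estimated correlation) and interferon and antigen presentation (0 of 15, 1 higher adjusted over the list alone, higher, 0.0256, then 0.342). The others, all lower and at 0.0281, were cell death and injury (0 of 14, 1 lower adjusted over the list alone, then 0.0892), immediate early genes (0 of 26, 0 adjusted over the list alone, then 0.445) and heat shock genes (0 of 22, 2 lower adjusted over the list alone, then 0.411). With 1 array left out the calls were lost for reactive astrocytes without kainate replicate 1, 2, 3 or 5 or nicotine replicate 1, 4 or 6 (adjusted p up to 0.153, with medians from −0.01 to 0.14), interferon without kainate 2 or 4 or nicotine 4 (0.1), and cell death without kainate 1 or 4 or nicotine 1, 3 or 6 (0.107). They were lost for immediate early genes without kainate 4 or 5 or nicotine 1, 2 or 3 (0.2) and for heat shock genes without kainate 4 or 5 or nicotine 1, 3 or 4 (0.271). Of 16 other alternatives, 7 ended the call of cell death and injury (range 0.0183 to 0.319), 6 that of reactive astrocytes (0.000259 to 0.138), 5 that of interferon (0.00965 to 0.481), 3 that of heat shock genes (0.00829 to 0.411) and 2 that of immediate early genes (0.000122 to 0.474). By fry the glucocorticoid list (adjusted p = 0.0533, range 8.97e-08 to 0.0533) and the microglia list (0.0646) were not called, nor was the latter in the largest cluster (range 4.22e-06 to 0.0845). Without kainate replicate 1, 2 or 4 or nicotine replicate 1 or 5 the count fell to 1, and the adjusted p of Wfs1 was up to 0.0872. S100a6 was lost without those arrays and without nicotine replicate 3, 4 or 6 (up to 0.179), and without kainate replicate 5 the count was 5. Wfs1 (range 0.00237 to 0.435) and S100a6 (0.0044 to 0.575) each lost their calls in 4 of 14 other alternatives, median centring and only the 2 groups among them. Gfap lost its call in the largest cluster (0.131, range 4.25e-06 to 0.131), where its log2 fold change was 1.18.

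The fold changes of kainate and of nicotine share their saline arrays. With all groups simulated as unchanged, saline included, the mean correlation was 0.475 in each region. The simulation drew each probe set independently and left out correlation between genes and the control clusters. Differences from its values therefore do not by themselves measure a shared drug effect. The observed Pearson correlation across 8695 probe sets was 0.58 in the neocortex (Spearman 0.583) and 0.409 in the hippocampus (Spearman 0.461). The observed covariance was 0.0334 against a simulated 0.0222 in the neocortex, a difference of 0.011, and 0.032 against 0.0244 in the hippocampus, a difference of 0.0076. With 3 saline arrays given to each drug, over 20 splits, the mean correlation was 0.074 in the neocortex (from −0.06 to 0.157) and 0.061 in the hippocampus (from −0.007 to 0.091).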

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

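The 9 counts of other splits and the first test of carried-over hippocampal tissue were fixed before their results were seen. The cluster fits, the blocked split counts and the later tests of carried-over tissue were chosen only after the result was seen. So were the tests of neuron share, blood, interneuron loss and scaling.

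The signals of 20 genes, chosen after their results were seen, and the median signal of each array were inspected in 6 groups. In 10 of 126 such combinations 1 array stood far from the others of its group, where chance gives about 5%. The gap to the nearest array, as a share of the group's range, was 0.86 for Bdnf in the nicotine neocortex (replicate 6 at 1697, the others 2747 to 2918) and 0.834 for H2-D1 in the saline neocortex (replicate 1 at 3272, the others 1159 to 1509). For Cst7 it was 0.667 in the saline neocortex (replicate 2 at 125.2, the others 21.7 to 56.2), 0.766 in the nicotine neocortex (replicate 6 at 16.8, the others 33.5 to 38.6) and 0.89 in the nicotine hippocampus (replicate 3 at 304.9, the others 29.3 to 59.7). C1qa in the saline hippocampus gave 0.658 (replicate 1 at 2646, the others 3180 to 3457). Sst gave 0.829 in the kainate hippocampus (replicate 1 at 5288, the others 6355 to 6576) and 0.747 in the nicotine hippocampus (replicate 6 at 10880, the others 8563 to 9149). Calb1 gave 0.765 in the kainate neocortex (replicate 3 at 3390, the others 2990 to 3084) and 0.685 in the nicotine hippocampus (replicate 3 at 1916, the others 2489 to 2752).

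The effect of kainate differed between hippocampus and neocortex for 69 probe sets by the test of the difference. The differences in log2 fold change were 2.842 for Mpeg1, 2.743 for Ifit3, 2.512 for Cd52, 1.928 for H2-K1, 1.918 for Lgals3bp and 1.721 for H2-D1. They were −0.911 for Msmo1, −0.899 for Idi1, −0.876 for Wfs1, −0.795 for Calb1, −0.577 for Cdk14 and −0.52 for Cpne6. Median differences of lists were 1.314 for microglia and macrophages, 1.003 for interferon and antigen presentation, 0.357 for glucocorticoid targets, 0.348 for reactive astrocytes, 0.345 for cell death and injury, 0.297 for astrocytes, −0.44 for cholesterol synthesis and −0.116 for oxidative phosphorylation. Some of these medians moved by over 1.5 times. That of glucocorticoid targets was 0.146 without kainate neocortex replicate 4 and 0.22 without saline hippocampus replicate 4. With the 50th percentile filter cell death and injury was 0.042 and reactive astrocytes 0.654. With median centring astrocytes were 0.196 and oxidative phosphorylation −0.217, and the latter was −0.076 with quantile normalization.

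Arrays were regrouped at random, 100 splits per comparison with the real one included, and the called probe sets counted. The real split alone reached its count for kainate against saline in the hippocampus (1 split as large, 243 real, 119 highest other). The same held for kainate against nicotine in the hippocampus (1, 210, 86) and hippocampus against neocortex (1, 917, 313), which argues against chance for these counts. Their highest other splits kept 1 of 11, 1 of 11 and 2 of 12 labels, close to the real grouping with its group names exchanged. For kainate against nicotine in the neocortex (1, 3, 2) the highest other lay close to the real count and kept 1 of 11 labels too. With 347 at an unadjusted p under 0.05, where 435 would be expected, that count alone does not exclude chance. For the regional difference of the kainate effect (3, 69, 307), 3 of 100 splits, the real one included, reached the real count. A split that kept 10 of 22 labels called 307, several times the real count, so this count alone does not exclude chance. That split called 81 with the control cluster as a block, against 102 for the real one, so its count depends on the clusters. For kainate against saline in the neocortex chance was not excluded as a count (9, 1, 37). The split with 37 called 62 with the cluster block, and whether either split follows another structure of the samples was not tested. With 0 called by limma (835, 504 and 328 at an unadjusted p under 0.05, and 0 with array weights), 100 of 100 splits were as large for nicotine against saline in the neocortex (highest other 8), in the hippocampus (4) and for the regional difference of the nicotine effect (2). A real count of 0 fixes that result in advance, so it decides nothing about chance.

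Microglia and macrophage genes had a median log2 fold change of 1.60 in the kainate hippocampus. Batch linked to treatment was not tested, since each control cluster held all treatments (median 1.624 with the cluster block, 1.52 in the largest). A lower share of neurons would raise other cell types alike, but the microglial mean exceeded that of myelin and endothelial genes by 1.564 ± 0.0816 (SE). More blood was argued against by a haemoglobin change of −0.067 ± 0.126 (SE, 4 probe sets). A response of microglia to kainate, or an influx of macrophages, may account for the rise, a hypothesis that these lists cannot split further.

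Gfap rose in the kainate neocortex, and hippocampal tissue carried over into those samples would need 11.8% of their RNA to explain it. Genes enriched in the saline hippocampus changed there by 0.165 ± 0.0568 (72 probe sets, 0.246 needed), which leaves it open, but they were picked with the same saline neocortex arrays, a bias toward a rise. Genes enriched in the nicotine hippocampus changed by 0.08 ± 0.0437 (58 probe sets, 0.251 needed, a shortfall of −0.166 ± 0.0597 averaged over arrays, each with its own Gfap share), which argues against carry-over as the whole cause. Genes more than 2-fold higher in the kainate hippocampus changed by 0.242 ± 0.0424 (61 probe sets, 0.346 needed, −0.0971 ± 0.0674 in the same way), which does not exclude it, and did so only before the error of the 11.8% was added to the spread, a step taken after the result was seen. Batch was argued against, with Gfap at 1.084 ± 0.137 with the cluster block and 1.37 ± 0.173 in the largest cluster, so an astrocyte response and some carried-over tissue may both remain, and the tests of the latter differ.

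Sst and Cort fell in the kainate hippocampus by a mean log2 fold change of −0.979 ± 0.147. Loss of interneurons as a class at that size was argued against, since Gad1 and Gad2, enzymes of GABA synthesis, had a mean of −0.048 ± 0.13, higher by 0.931 ± 0.143. With Slc32a1 (−0.43 ± 0.106), which fell, the mean of the 3 was −0.176 ± 0.113, still higher by 0.803 ± 0.13, but Gad1 (−0.31 ± 0.093) and Gad2 (0.22 ± 0.222) differed, so a smaller loss of interneurons as a class stays open. The scaling was argued against by −1.017 ± 0.161 with quantile normalization. Batch was again untested (−0.961 ± 0.133 with the cluster block). Loss of the Sst neurons alone, or lower expression in them, may each account for the fall and was not tested.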

How the results depend on the processing

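The alternatives built on hybridization-control clusters or on the least correlated arrays were chosen only after the result was seen. No named gene changed sign and no list changed its test direction in a call under any alternative run. A median could still change sign within a call. That of reactive astrocytes, kainate against nicotine in the neocortex, was 0.008 in the main fit. It was −0.013 without nicotine replicate 5, where camera still called the list (adjusted p = 0.0387). The balance of calls turned for kainate against saline in the hippocampus with median centring (160 higher and 83 lower, then 130 and 313). It turned slightly for the saline regions (466 higher and 451 lower) with quantile normalization (434 and 441) and array weights (449 and 465). For kainate against saline in the neocortex (1 called) the count was 2 with quantile normalization, 2 with array weights, 3 with the replicate block, 6 with the cluster block, 2 in the largest cluster and 2 without the brightest cluster. For kainate against nicotine in the neocortex (3) it was 1 with median centring, 8 with array weights, 1 with only the 2 groups compared, 5 with the replicate block, 8 with the cluster block and 0 in the largest cluster. That 0 by limma, from 3 arrays per group, came with 341 at an unadjusted p under 0.05, and leaving out 1 array gave 1 to 5. In the hippocampus, kainate against saline (243) gave 443 with median centring and 54 in the largest cluster, and kainate against nicotine (210) gave 47 in the largest cluster, where fewer arrays were tested. The correlation between the regions of the nicotine effects was 0.305 with the 50th percentile filter against 0.164. Apart from the smaller clusters, the cause was not tested. Every other count run stayed within 1.5 times of its reported value, with leave-one-out ranges of 178 to 243 for kainate against saline in the hippocampus, 155 to 209 for kainate against nicotine there, 48 to 79 for the regional difference of the kainate effect and 759 to 891 for the saline regions. Against saline in the kainate hippocampus the replicate block called Fos (0.0331, range 0.0331 to 0.533), Npy (0.0447, range 0.0178 to 0.473), Gria2 (0.0265, range 0.0046 to 0.388) and the brighter Ssbp4 probe set (0.0331, range 0.0138 to 0.449), and ended the call of the dimmer (0.0528, range 0.0147 to 0.212). In the kainate neocortex it called Ctss (0.0408, range 0.00139 to 0.48) and Nr4a1 (0.00154, range 0.000758 to 0.905). Against nicotine it called Ctss in the neocortex (0.0319, range 0.00231 to 0.435) and Fkbp5 in the hippocampus (0.0464, range 0.0464 to 0.287). With the same number in both regions taken as 1 mouse, 59 (fixed) and 70 (random) probe sets differed between the regions, the calls of Egr1 (0.0204, range 0.0204 to 0.254) and Penk (0.0221, range 0.00876 to 0.137) were gained and that of Cpne6 (0.074, range 0.00391 to 0.0988) was lost with the fixed block, as were those of Mt1 (0.131, range 0.00419 to 0.299), Mt2 (0.113, range 0.00732 to 0.239) and Ighm (0.059, range 0.00272 to 0.0822). The replicate block moved no further count by more than 1.5 times. Same-numbered arrays of different treatments deviated together in part. Their mean correlation was 0.062 over 16 pairs in the neocortex (−0.011 for other pairs) and 0.11 over 16 in the hippocampus (−0.022). Across regions it was 0.005 over 17 pairs of the same treatment and number. Of 17 arrays, 6 in the neocortex and 10 in the hippocampus correlated best with their own number. The control clusters followed the numbers. Hippocampal replicate 1 of each treatment lay in 1 cluster and replicates 2 to 4 in another, and neocortical replicates 1 to 3 shared 1. Number and cluster thus overlap as blocks. Since the labels do not say what a number marks, numbers were not taken as pairs. Among the named genes, alternatives fixed in advance left 3531 values on the same side of the threshold, ended 51 calls and added 32. Leaving out 1 array left 4337, ended 197 and added 10, and alternatives chosen later left 762, ended 77 and added 14. Among lists these numbers were 2558, 68 and 68, then 2642, 62 and 50, then 480, 21 and 12. The call of Cort against nicotine in the hippocampus was lost without the 2 least correlated arrays (adjusted p = 0.0503) and with only the 2 groups compared (0.0549), in a range of 0.000881 to 0.511. Alternatives that took a named gene below the filter gave no value for it, 9 for Cst7 and 8 for Lyz2 against saline. Array number limits the precision, and dim probe sets are limited by their signal over background.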

Other observations

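The tests without the 2 least correlated arrays and in the largest control cluster were chosen only after the result was seen. The genes below were also selected after their values were seen, from those named by rule.

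In the hippocampus, kainate and nicotine mice differed in several neuronal genes by limma. Npy, the neuropeptide Y precursor, was higher with kainate than with nicotine (3165 ± 208 against 2497 ± 211, log2 fold change 0.34, adjusted p = 0.038), and so was Penk (0.89, 0.00141). Lower with kainate were Sst (−0.56, 0.000643), Slc32a1 (−0.55, 0.00367), Calb1 (−0.64, 0.000448), Cck (−0.43, 0.00112) and the AMPA receptor subunit Gria1 (7046 ± 590 against 9075 ± 602, −0.37, 0.0277). In each of these the 5 kainate arrays lay beyond all 6 nicotine arrays, which choosing called genes favours. Of all 8695 probe sets, 254 were so separated, where 37.6 would be expected from random regrouping (0.433%). Other probe sets gave 0.42 for Penk (adjusted p = 0.64) and −0.30 for Gria1 (0.38). The Npy call was lost without kainate replicate 1, 2, 4 or 5 or nicotine replicate 2, 4, 5 or 6 (adjusted p up to 0.121), with median centring (0.149), with only the 2 groups compared (0.057), without the 2 least correlated arrays (0.0527) and in the largest cluster (0.571, range 0.00928 to 0.571). The Gria1 call was lost without kainate replicate 1, 2, 4 or 5 or nicotine replicate 2, 3, 4 or 6 (up to 0.0918), with quantile normalization (0.0656) and in the largest cluster (0.336, range 0.0102 to 0.336). The largest cluster, with 3 arrays per group, also ended the calls of Penk (range 0.00113 to 0.242), Sst (0.000107 to 0.0923), Slc32a1 (0.000473 to 0.319), Calb1 (2.46e-06 to 0.0678) and Cck (0.000264 to 0.157).

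Between the saline regions, microglia and macrophage genes showed no called member among 21 (0 adjusted over the list alone, median 0.05, camera direction lower, adjusted p = 0.995). Dentate granule genes had 3 of 7 members higher and 1 lower in the hippocampus (3 and 2 adjusted over the list alone, median 0.43), and the list was not called (adjusted p = 0.0771), though it was by fry and with no filter (range 7.53e-06 to 0.152). With 1 array left out its median ran from 0.15, without saline neocortex replicate 2, to 0.67, without saline neocortex replicate 6. Of 9 GABA receptor genes 1 was higher and 3 were lower (1 and 3 adjusted over the list alone, adjusted p of the list 0.431, called by fry alone at 0.0221, range 0.0221 to 0.617).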
